A study of Mus musculus with 6 samples.

How the data were processed

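The series holds 6 libraries from undifferentiated P19 cells, a mouse embryonal carcinoma line: 2 with an antibody to crotonylated and 2 with an antibody to acetylated lysine 9 of histone H3, and 2 inputs. Chromatin was prepared and precipitated without crosslinking, per the labels' protocols, and the marks each have 2 biological replicates, per the series design text. Groups and replicate numbers were taken from the labels. The inputs were not analysed here, and neither read depth nor the pairing of inputs with precipitated libraries is given in the sources used here. Each mark was measured with a single antibody, so a property of an antibody and a property of its mark cannot be told apart.

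The authors deposited 1 peak list per library. Bowtie2 2.4.1 and MACS2 2.2.7.1 were used with the build GRCm38, per the submitters' processing notes; the options are not given in the sources used here. Per the file headers, each row gives a chromosome, a start, an end, a length and the position of the summit. Pileup is the coverage signal at the summit, per the file headers. Its typical step, the median of the first differences between sorted values, was 0.94, 0.71, 1 and 0.98 in the H3K9cr and H3K9ac libraries in order of replicate. The values therefore appeared to be scaled in all libraries but H3K9ac replicate 1. The deposited -log10 p-value and -log10 q-value come from the authors' peak caller, as does the deposited fold enrichment, a ratio of pileup to local background. In every list the q-value was at most about 0.01, as the smallest -log10 q ranged from 2.02 to 2.06. Per-peak values of the authors were used to describe, rank or filter peaks within a list, and only their ranks were compared between libraries. Ranks across shared regions were compared by Spearman's rho. Ranks of the summit pileup were also converted to normal scores, correlated as differences between marks, and fitted with limma by mark and by the regrouped splits. Weak sites below the authors' threshold are absent from a list, so a missing peak is not a measured absence of the mark. Longer lists and wider peaks follow from deeper sequencing as well as from more signal, which the lists cannot separate.

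Positions were compared in GRCm38, the build of both the lists and the gene table, counted from 1. Overlap means at least 1 bp. Peaks of the 4 libraries were merged into regions, which were called shared when all 4 libraries had a peak, and specific to a mark when both libraries of that mark and neither of the other had one. As a background, the same rule was applied to the other 2 of the 3 ways of dividing 4 libraries into pairs. The gene table gives no strand, transcript or sequence, so the planned window around a gene's 5' end was replaced by 1 kb around either end of the gene record, exons and introns were replaced by the gene body, and the planned count of any transcript start and of promoter CpG content was not run. A mark at a gene end is therefore not always at a promoter, and promoters inside a gene record would be missed. Covered length was taken within 2.5 kb of whichever end had the higher mean over the libraries. The 21887 protein-coding genes formed the background.

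Single values were compared by exact two-sided permutation of 2 libraries against 2, for which the smallest p is 0.333. The 24 gene lists, fixed before the data were examined together with the comparisons and most alternatives, were tested with Fisher's exact test, with Benjamini-Hochberg adjustment over 48 tests. Every list member asked for was matched. Covered length was centred on the library median and fitted with limma 3.58.1 in R 4.3.3 at an adjusted p of 0.05, and lists of at least 5 measured members were tested with camera at a correlation of 0.01 and at an estimated correlation. Overlaps used bedtools 2.31.1, and other steps Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The local background implied by a peak was computed as its pileup plus 1, divided by its fold enrichment, minus 1.

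Genes were named by a fixed rule: the 10 genes of each mark alone with the highest fold enrichment in the weaker replicate, up to 5 genes per direction past the threshold for covered length (there were 0), a fixed set of pluripotency, lineage, housekeeping and acylation genes, and up to 4 members of each list that passed, those with 1 mark alone or with the largest difference in covered length. Some genes that the rule takes are not reported here. The methods were tested on simulated data. Of 200 and 100 regions planted for one mark alone, 200 and 100 were found, and 0 of 200 random lists were called. The simulated lists held well-separated peaks of a single library, shifted slightly and without the replicate disagreement of the real lists. Random lists were drawn gene by gene, without genes chosen to share a peak. Both outcomes therefore check the code and not the real calls. Among 14110 simulated genes, limma made 2 false calls.

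The alternatives tried were peaks with a q of at most 1e-05, equal numbers of peaks (26096), reciprocal overlap of at least 50%, a window of 2.5 kb, autosomes alone, leaving out each library, the replicate number as a block, no centring, a log2 scale and a window of 5 kb for covered length. Added after the data were seen were the gene span with 1 kb either side and the strongest 15000 peaks. The 4 lists shared only 10 to 23 identical intervals per pair, so no library appeared to be present in duplicate.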

Results

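Crotonylation and acetylation of lysine 9 of histone H3 (H3K9cr and H3K9ac) were profiled by native chromatin immunoprecipitation and sequencing in P19 cells, a mouse embryonal carcinoma line that is kept undifferentiated in proliferation medium. Each mark was measured in 2 biological replicates, and each of these 4 libraries had its own list of peaks. The 2 input libraries of the series were not analysed here. The H3K9cr lists held 28360 and 28345 peaks and the H3K9ac lists 26096 and 27474 peaks. Read depth was not given in the sources used here, so no interval that needs it is given. The series title names the profiling of both marks, so the question was where the 2 marks lie in the same cells, and each difference between marks was set against the difference between replicates of a mark.

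H3K9cr and H3K9ac occupied largely the same part of the P19 genome. The longest or next longest peak of every library lay over the gene of the histone demethylase Kdm6b (13754 to 13949 bp, chosen after its values were seen, in the region at chromosome 11, 69408176 to 69422124, GRCm38), and peaks of both marks lay at the ends of the pluripotency genes Pou5f1, Sox2 and Nanog in all 4 libraries. H3K9cr peaks covered 41.6 Mb ± 0.652 (SD, n = 2) and H3K9ac peaks 38.2 Mb ± 2.51 (SD, n = 2). Summits lay within 1 kb of an end of a protein-coding gene for 42.7% ± 0.169 of H3K9cr peaks and 45.6% ± 2.01 of H3K9ac peaks (SD, n = 2 each), whereas such positions make up 2.91% of the span considered. A further 30.6% of H3K9cr and 29.2% of H3K9ac summits lay inside the bodies of protein-coding genes, and 26.7% and 25.2% lay outside protein-coding genes.

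The mean number of peaks was 28352.5 ± 10.6 for H3K9cr and 26785 ± 974 for H3K9ac (SD, n = 2 each). Both H3K9cr libraries had more peaks and a larger covered length than both H3K9ac libraries, for which the exact two-sided permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow. Median peak length was 1227 bp ± 26.9 for H3K9cr and 1206.5 bp ± 30.4 for H3K9ac (exact permutation p = 0.667, n = 2 each). In single libraries, the share of summits at a gene end was 42.9% (95% Wilson interval 42.3 to 43.4) and 42.6% (42.1 to 43.2) for H3K9cr, and 47.0% (46.4 to 47.6) and 44.1% (43.6 to 44.7) for H3K9ac. The H3K9ac replicates thus differed from each other by about as much as the marks did, and with equal numbers of peaks the 4 shares were 45.7%, 45.4%, 47.0% and 45.9%.

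Most sites were common to the 2 marks, and sites listed for one mark alone carried weak peaks. Merging the peaks of all 4 libraries gave 31127 regions, of which 22972 (73.8%) had a peak in every library. H3K9cr was listed without H3K9ac, in both replicates, at 801 regions, and H3K9ac without H3K9cr at 87 regions. Peaks of the first H3K9cr library in regions with a peak in both H3K9ac libraries had a median fold enrichment of 27.2, as the authors' peak caller gave it. Peaks in regions with neither H3K9ac library had a median of 4.87. The corresponding medians were 26.6 and 4.57 in the second H3K9cr library, 20.5 and 4.26 in the first H3K9ac library, and 26.2 and 4.70 in the second.

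Peaks in regions with both libraries of the other mark, called shared peaks in this paragraph, were also longer. In the first H3K9cr library their median length was 1455.5 bp against 328 bp for peaks without H3K9ac, and in the first H3K9ac library it was 1251 bp against 299 bp. A shared peak had the higher fold enrichment in 94.1% to 95.8% of all pairs of a shared and an unshared peak within a library. The fold enrichment of peaks in regions of one mark alone reached at most 15.7, and 100% of them lay below the median of their own list. The lists hold only peaks past a threshold, and peak strength was ranked much alike in all libraries. Peaks missing from other lists would therefore tend to be weak under any grouping. Peak strength was not compared for the regrouped libraries, so the weakness is not shown to be particular to the marks.

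The marks overlapped about as much as replicates did. The Jaccard index in base pairs was 0.853 between the H3K9cr replicates and 0.831 between the H3K9ac replicates, and it lay between 0.810 and 0.861 for the 4 pairs of different marks. The mean was 0.842 for pairs of the same mark and 0.836 for pairs of different marks. Of the peaks of each H3K9cr library, 92.6% and 91.9% overlapped the other replicate, and of the H3K9ac libraries 95.3% and 87.7% did. The same rule of both libraries against neither, applied to libraries grouped by replicate number, gave 244 and 602 regions, and applied to the crossed grouping gave 356 and 152. The total for the grouping by mark was 888 regions, compared with 846 and 508 for these regroupings. When the strongest 26096 peaks of every library were used, H3K9cr-only regions numbered 429 and H3K9ac-only regions 185, a total of 614, and the grouping by replicate number gave 793.

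**Figure D1:**
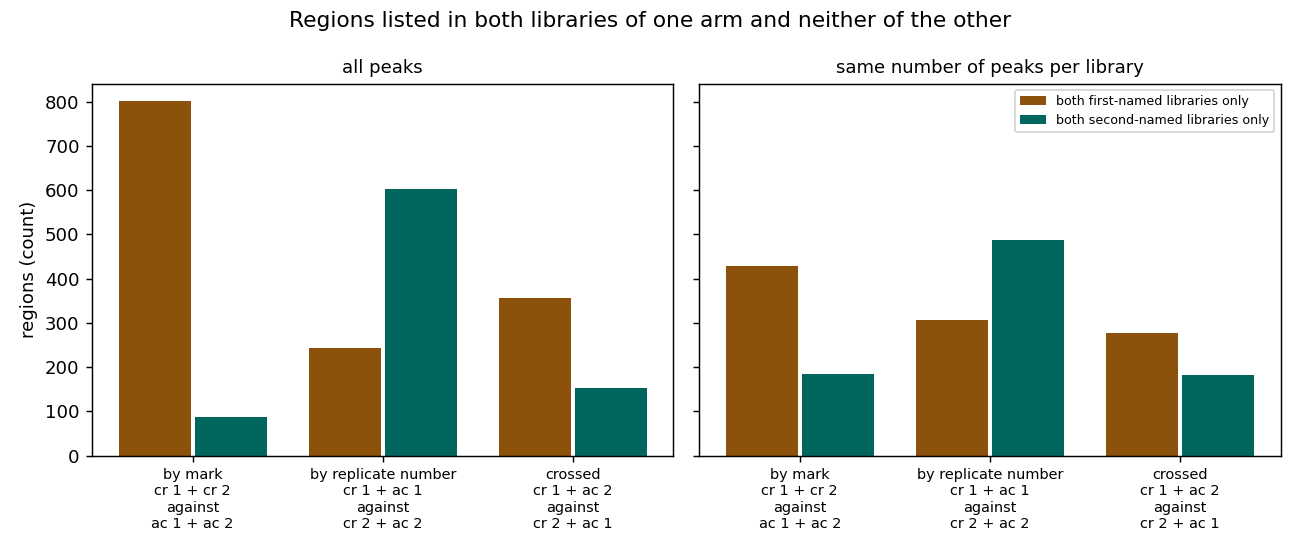
Number of regions (vertical axis, count) listed in both libraries of one arm and in neither library of the other, for the 3 ways of dividing the 4 libraries into pairs, with all peaks (left) and with equal numbers of peaks (right). Bars give counts without error. The total by mark was 888 regions with all peaks and 614 with equal numbers, and the total by replicate number was 846 and 793.

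Across the 22972 shared regions, strong sites of one mark were strong sites of the other. Spearman's rho of the authors' fold enrichment was 0.939 and 0.941 between replicates of a mark. It was 0.975 and 0.980 between libraries of different marks with the same replicate number, and 0.938 and 0.937 between those with different numbers. For the height of the pileup at the summit, the mean rho was 0.988 for the same mark, 0.985 for the same number and 0.985 for neither. These values are across regions, which are not independent replicates.

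**Figure D2:**
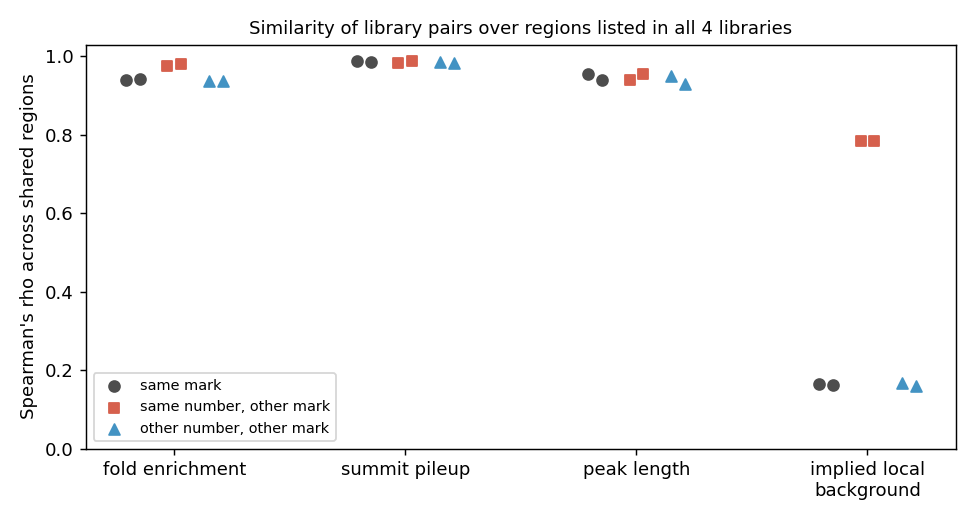
Spearman's rho across the 22972 regions shared by all libraries (vertical axis, no unit) for each of the 6 library pairs, for 4 properties of a peak. Each point is 1 pair, and symbols give the kind of pair. Pairs with the same replicate number had a rho of 0.784 and 0.783 for the implied local background, and the other pairs lay between 0.161 and 0.167.

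At gene level, 13462 of 21887 protein-coding genes (61.5%) carried both marks at an end in every library, and 7863 (35.9%) carried neither. Pou5f1, which encodes the pluripotency factor Oct4 (chromosome 17, 35506032 to 35510777, GRCm38), had a fold enrichment of 71.9 ± 8.54 in the H3K9cr libraries and 69.9 ± 10.2 in the H3K9ac libraries (SD, n = 2 each). Sox2, its partner factor (chromosome 3, 34649995 to 34652461), had 90.0 ± 0.598 and 76.7 ± 19.8, and Utf1, an embryonic stem cell chromatin factor, had 90.1 ± 5.58 and 80.3 ± 18.7. Lin28a, an RNA-binding protein of undifferentiated cells, had 48.9 ± 7.20 and 58.5 ± 0.808. Nanog (chromosome 6, 122707489 to 122714633) was weaker, with 13.9 ± 1.84 for H3K9cr and 6.49 ± 3.03 for H3K9ac. A fold enrichment is ranked only within its own list, so no change between marks is read from these values.

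Several genes of differentiated lineages also carried both marks, with a lower fold enrichment than Pou5f1. The neural genes Pax6 and Neurog1, which encode transcription factors of neural development, ranged over the 4 libraries from 9.71 to 12.01 and from 5.74 to 7.33. Sox1, a marker of neural progenitors, ranged from 17.8 to 33.4. The mesoderm factor T ranged from 11.96 to 17.9 and the endoderm factor Sox17 from 9.56 to 12.03. Hoxb1 lay between 6.83 and 14.2. The housekeeping genes Gapdh (152 to 228) and Actb (105 to 150.0) were higher, as were the acetyltransferase gene Ep300 (86.3 to 165) and the deacetylase gene Hdac1 (91.1 to 139). Alb and Hbb-bt, which encode serum albumin and an adult beta globin, had no peak at an end or within the gene in any library. Gata4 and Cdyl had no peak at an end, but peaks within the gene in all 4 libraries, with fold enrichment from 11.97 to 13.9 at Gata4 and from 142 to 214 at Cdyl.

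Few genes carried one mark alone. H3K9cr without H3K9ac was found in both replicates at 47 genes and the reverse at 11 genes, a total of 58, whereas grouping the libraries by replicate number gave 69 genes and the crossed grouping 41. With equal numbers of peaks the counts were 33 and 27. The 10 H3K9cr-only genes with the strongest peaks in the weaker replicate were Tars2, Septin11, Tmem274, Rasal3, Ak8, Vmn1r210, Acp5, Cyp2f2, Gucy1b2 and Lsp1. Tmco5 (6.16 and 20.8) tied with Gucy1b2 and Lsp1 in the weaker replicate and was left out by alphabetical order. The 10 H3K9ac-only genes taken likewise were Zmym4, Cxcr5, Ephx2, Nectin4, Slc28a3, Kctd19, Lrrc36, Slc10a4, Hoxd12 and S100a16, of which Kctd19 and Lrrc36 had the same peak at a common end. Tars2, a mitochondrial threonyl-tRNA synthetase (chromosome 3, 95739974 to 95756365), had H3K9cr fold enrichments of 115 and 130, and Zmym4 (chromosome 4, 126861819 to 126969377) had H3K9ac fold enrichments of 94.2 and 101.

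At the strongest of these genes the peak of the other mark stopped just short of the window. At Tars2 the nearest H3K9ac peak of both libraries lay 105 bp outside the 1 kb window, at Rasal3 111 and 121 bp, at Ak8 22 and 12 bp, and at Zmym4 the nearest H3K9cr peaks lay 181 and 136 bp outside it. Of the 47 H3K9cr-only genes, 11 had a peak from a region shared by all libraries, and of the 11 H3K9ac-only genes 2 did. Genes whose peaks lay in regions of one mark alone numbered 31 and 7, with a fold enrichment of at most 6.28 and 5.42 in the lower replicate. Examples were Cyp2f2 with 6.28 and 7.40 for H3K9cr, whose nearest H3K9ac peaks lay 25615 and 30773 bp beyond the window, and Ephx2 with 5.42 and 6.35 for H3K9ac. With a window of 2.5 kb, 28 of the 47 and 8 of the 11 genes remained in their class.

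Genes for basic cell functions carried both marks almost throughout, and olfactory and vomeronasal receptor genes hardly carried any. Both marks were found in every library at 78 of 81 cytosolic ribosomal protein genes (96.3%, adjusted p = 2.15e-12), 76 of 78 mitochondrial ribosomal protein genes (97.4%, 6.03e-13), 37 of 38 cell cycle and DNA replication genes (97.4%, 1.43e-06) and 72 of 78 oxidative phosphorylation genes (92.3%, 7.81e-09). The 3 cytosolic ribosomal genes without a peak were Rpl10l, Rpl32l and Rpl39l. Proteasome genes (36 of 39, 7.57e-05), glycolysis and TCA cycle genes (31 of 34, 4.45e-04) and replication-dependent histone genes (57 of 62, 5.80e-07) were similarly occupied. Of 1106 olfactory receptor genes 0 carried both marks in every library, and of 353 vomeronasal receptor genes 1 did (adjusted p = 6.06e-145). Keratins and keratin-associated proteins (9 of 104, 1.80e-28) and germline genes (4 of 25, 1.58e-05) were also occupied less than other genes.

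Regulators of development and of chromatin were occupied as well. Both marks lay at 27 of 28 neural progenitor genes (96.4%, adjusted p = 1.30e-04), all but Msi1, which had a peak within the gene in every library, and at 21 of 24 neuronal and synaptic genes (87.5%, 0.0256). They lay at 64 of 70 developmental regulators known as Polycomb targets in stem cells (91.4%, 1.21e-07), with a median fold enrichment at the 39.6th to 43.7th percentile of the lists. Cytosolic ribosomal protein genes stood at the 97.2nd to 98.0th percentile and pluripotency genes at the 68.5th to 77.1st. Enzymes, readers and metabolic genes of crotonylation were occupied at 32 of 34 genes (94.1%, 8.00e-05), all but Cdyl and Taf1, both with a peak within the gene in every library, and acetylation, Polycomb and Trithorax regulators at 24 of 27 (88.9%, 0.00712). Zinc finger genes of the Zfp series (324 of 394, 3.32e-18) and protocadherin genes (51 of 57, 1.58e-05) also exceeded the other genes. The 51 protocadherin genes fell into 31 groups with no region in common, of which the largest had 21 genes, and the 57 histone genes into 32 groups, so these tests count some peaks for several genes.

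The remaining lineage lists did not exceed other genes past the threshold. Pluripotency genes were occupied at 27 of 34 (79.4%, against 61.5% of other genes), which did not pass (adjusted p = 0.0777), and the 7 without both marks in every library included Zfp42, Esrrb, Dppa5a and Prdm14. Hox genes were occupied at 31 of 39 (79.5%, adjusted p = 0.0502). Mesoderm and muscle genes (13 of 24), endoderm and trophectoderm genes (12 of 22) and fibroblast markers (9 of 16) each had an adjusted p of 1, and blood cell markers were occupied less often (5 of 18, 0.0155). These are two-sided Fisher's exact tests across genes, which are not independent replicates, adjusted by Benjamini and Hochberg over 48 tests, and 19 of 24 lists passed, 14 above and 5 below other genes. With a window of 2.5 kb, pluripotency (88.2%, adjusted p = 0.00862) and Hox genes (89.7%, 0.00170) passed and blood cell markers (44.4%, 0.198) did not. Hox genes also passed without H3K9cr replicate 2 or H3K9ac replicate 2 (82.1%, adjusted p = 0.0201 each), but stood at 66.7% (adjusted p = 1) with the stricter threshold and 74.4% (0.232) with equal numbers of peaks.

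Genes with one mark alone were too few to compare the lists by Fisher's exact test, since no list held more than 1 such gene and the smallest p reached was 0.190. The members with one mark alone included Vmn1r210 with H3K9cr fold enrichments of 11.3 and 11.5. Its nearest H3K9ac peaks lay 340453 bp (replicate 1) and 107 bp (replicate 2) outside the window. Others were Slc17a6, a vesicular glutamate transporter gene with H3K9cr fold enrichments of 4.36 and 3.82, and Zfp445 with 4.22 and 5.68. Krt19 had 5.35 and 2.86, and Stra8, which germ cells need to enter meiosis, had 6.91 and 3.87. Hoxd12 carried H3K9ac with 4.26 and 3.91, and its nearest H3K9cr peaks lay 889 and 879 bp beyond the window, within reach of a window of 2.5 kb.

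**Figure D3:**
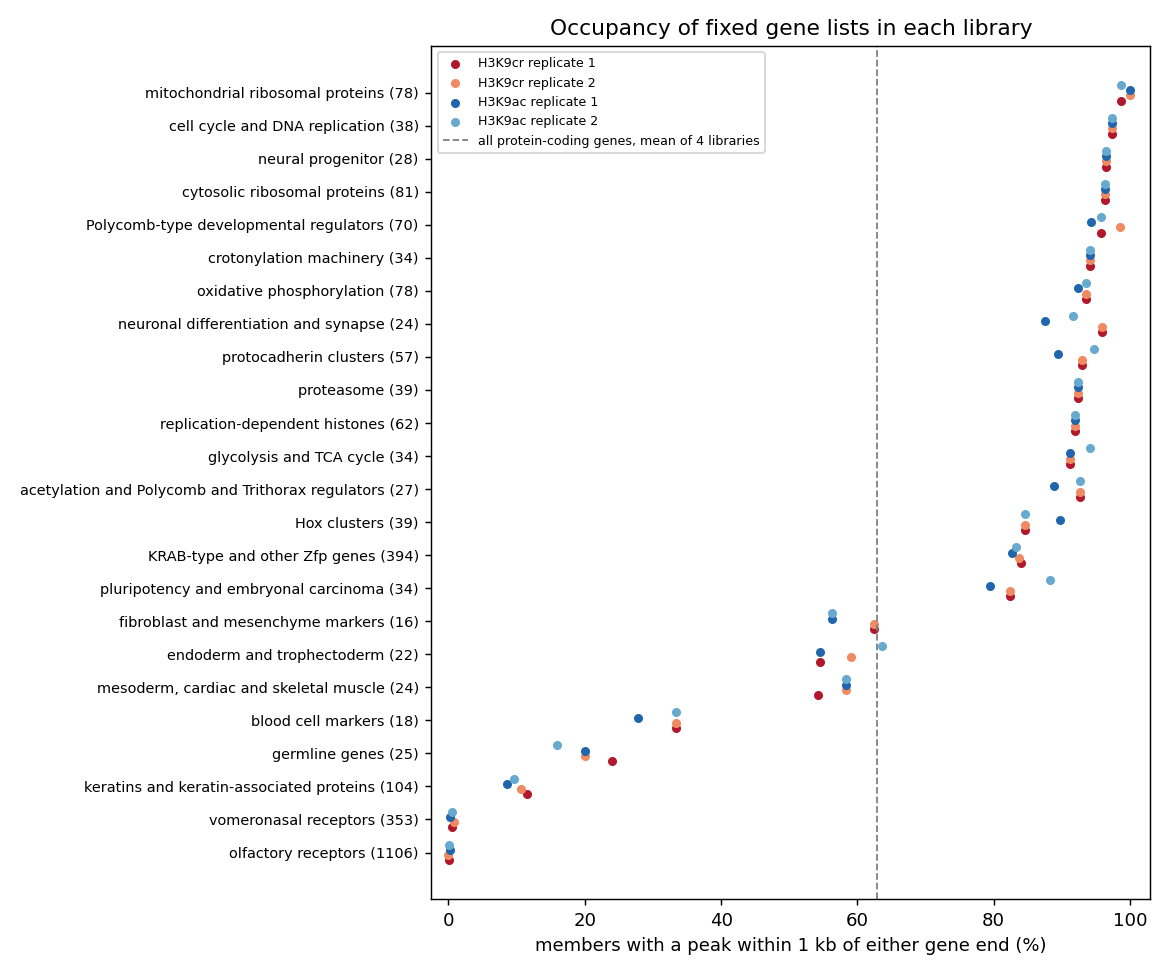
Share of each gene list with a peak within 1 kb of either gene end (horizontal axis, percent), with 1 point per library and the number of members in parentheses. The dashed line is the mean over all protein-coding genes. Cytosolic ribosomal protein genes stood at 96.3% in every library and olfactory receptor genes at no more than 0.181%.

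The length of DNA covered at gene ends was compared at 14110 genes with a peak in every library, as base pairs within 2.5 kb of the end relative to the median of the library. Median coverage was 2050 and 2087.5 bp for H3K9cr and 1921 and 2025 bp for H3K9ac. No gene passed in limma: 0 were wider for H3K9cr and 0 for H3K9ac, the smallest adjusted p was 0.683, and 702 genes (4.98%) had an unadjusted p under 0.05, of which 470 were wider for H3K9cr. Grouping the libraries by replicate number gave more, 959 genes (6.80%) with a smallest adjusted p of 0.181, and the crossed grouping gave 469. Without centring on the library median, 0 genes passed and 882 of 927 genes with an unadjusted p under 0.05 were wider for H3K9cr, since the median difference moved from -20.2 to 75.5 bp. On simulated data with this design, 0% of genes changed by 300 bp, 24% of those changed by 600 bp and 94% of those changed by 2400 bp were recovered. The simulated errors were normal and independent, with each gene's SD estimated from the replicates of its marks. Simulated lengths were not bounded by the window, as real ones are. The shares recovered are therefore only a rough guide to the power in the real data.

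As groups, the gene ends of 5 of 21 lists differed in covered length from the other genes in limma's camera test with a preset correlation of 0.01. Differences are H3K9cr minus H3K9ac after centring, which subtracted 95.75 bp from every gene. Against a median of -20.2 bp over all genes tested, the median was 73 bp for cytosolic ribosomal protein genes (adjusted p = 1.83e-04), 81 bp for replication-dependent histone genes (0.00260) and 48 bp for crotonylation genes (0.00859). Protocadherin genes (-100.0 bp, 0.00466) and Polycomb-type developmental regulators (-91.8 bp, 0.0355) lay on the other side of that median. With the replicate number as a block the developmental regulators had an adjusted p of 0.0563 in camera. With an estimated correlation the first 3 lists had an adjusted p of 0.484. Protocadherins and developmental regulators then had 0.825 and 0.824, so that 0 of 21 lists passed. The estimated correlations of the first 3 lists were 0.0110, 0.00591 and -0.00885, about the preset value or below it. Correlation between genes therefore does not account for the loss of these 3 calls. That form of the test rests on the spread of only 4 libraries and has little power here. The estimated correlation was 0.528 for protocadherins and 0.0570 for developmental regulators, both above the preset value. At the preset value, camera therefore treated the genes of these 2 lists as more independent than they were. The protocadherins Pcdhgc5 and Pcdhgb7, for example, had the same covered length in each library. In uncentred base pairs the medians of protocadherin genes and developmental regulators were -4.25 and 4 bp, against 169 bp for ribosomal protein genes. Neither of these calls was specific to the marks: protocadherins passed when libraries were grouped by replicate number (adjusted p = 1.83e-04) and crossed (1.15e-05), and developmental regulators when crossed (0.00434). Adjusted over the list alone, 1 cytosolic ribosomal protein gene and 0 genes of the other 4 lists passed, against 0 over all genes tested, and so did 2 Hox genes, 2 fibroblast markers, 1 blood cell marker and 1 mesoderm or muscle gene, of lists that camera did not call.

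The members with the largest differences in covered length, H3K9cr minus H3K9ac relative to the library medians, were Rps4x (1327 bp ± 294, SE), Rpsa (660 ± 196), Rpl32 (602 ± 115) and Rps12 (590 ± 80.8) among ribosomal protein genes, and Dpf1 (692 ± 121), Kat2a (367 ± 80.3), Hdac1 (342 ± 84.4) and Acss2 (-290 ± 114) among crotonylation genes. Among developmental regulators they were Gsx1 (-1114 ± 301), Foxc2 (-774 ± 277), Lhx8 (-694 ± 171) and Nkx2-2 (564 ± 88.9), among histone genes H4c12 (651 ± 211) and H2ac15 (608 ± 232), and among protocadherins Pcdhb11 (234 ± 143) and Pcdhb15 (-204 ± 110). Within 5 kb of the end the difference was -132.5 bp at Hdac1 and 66.5 bp at Dpf1. Each rests on 2 libraries per mark, and none of these genes passed over all genes. Leaving out a single library brought the difference down to 338 bp at H4c12, 262.5 at H2ac15, 57 at Pcdhb11, -82 at Pcdhb15 and 870.5 at Rps4x (without H3K9ac replicate 1), -374 at Foxc2 (without H3K9ac replicate 2), -155 at Acss2 and -704 at Gsx1 (without H3K9cr replicate 2) and 405 at Rpsa (without H3K9cr replicate 1). In camera without H3K9ac replicate 1 the protocadherin median was 15 bp (adjusted p = 0.248), the crotonylation median 32.8 bp (0.397) and the histone median 23.5 bp (0.127), and without H3K9cr replicate 1 the medians of the latter lists were 36 bp (0.173) and 15.8 bp (0.0518). Without H3K9ac replicate 2 they were 126 and 168 bp. Developmental regulators had an adjusted p of 0.973 without H3K9ac replicate 2 and 0.114 without H3K9cr replicate 2.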

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

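These values were chosen after the peak lists had been seen, and concern gene classes and a site that no comparison of the marks was about. Among 8882 long noncoding RNA genes more than 5 kb from every end of a protein-coding gene, 952 (10.7%) had a peak of both marks at an end in every library. They included Snhg17, a host gene of small nucleolar RNAs, with a fold enrichment of 135 to 214 over the 4 libraries, and Malat1, an abundant nuclear RNA, with 102 to 144. Among 809 microRNA genes at that distance, 72 (8.90%) had such peaks, among them Mir148a (64.5 to 92.2) and Mirlet7i (59.2 to 127). Mir18 and Mir20a, neighbours on chromosome 14, both had 33.3 to 49.1.

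A single site stood apart in the local background implied by the peak caller's values. At chromosome 11, 3192682 to 3193860 (GRCm38), within Sfi1, the implied background was 52.0 and 56.0 in the H3K9cr libraries and 43.2 and 54.0 in the H3K9ac libraries, whereas the next highest values in these libraries were 11.2, 13.0, 10.4 and 14.0 and the medians lay between 1.73 and 2.07. The fold enrichment there was 3.80 to 4.41. No biological explanation was tested for it.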

How the results depend on the processing

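Of the alternatives, the strongest 15000 peaks and the gene span were chosen after the data were seen. Across 657 alternative values, 574 kept their direction and side of the threshold (tests), stayed within 1.5 times (counts) or moved less than the replicate spread. Among the main results 83 values stayed and 32 moved. The 83 include counts that were 0 and stayed 0 under every alternative. These were genes wider for either mark, and lists that differed between genes of one mark alone. Those tests had little power, so a count that stays at 0 says little about stability. The other 491 values that stayed belong to secondary results, such as single lists and genes. Equal numbers of peaks gave 429 H3K9cr-only and 185 H3K9ac-only regions and 27 H3K9ac-only genes, a replicate overlap of 93.2% for H3K9cr, and 45.6% of H3K9cr summits at a gene end. The strongest 15000 peaks gave 13780 shared and 132 H3K9cr-only regions. The stricter threshold gave a replicate overlap of 93.0% for H3K9cr and 44.9% (H3K9cr) and 47.8% (H3K9ac) of summits at a gene end, which were 51.5% and 54.6% with a window of 2.5 kb. Reciprocal overlap lowered replicate overlap to 86.5% and 83.9%. Leaving out a library, which loosens the rule of both libraries, gave 1162 to 2293 H3K9cr-only and 277 to 857 H3K9ac-only regions, 74 to 189 H3K9cr-only and 33 to 56 H3K9ac-only genes, and 2 to 4 lists past 0.05 for covered length, where the lone library was assumed to vary like the others. An estimated correlation left 0 such lists. Leaving out a library, the median for developmental regulators ranged from -156.5 to -57.2 bp, and at -109 bp without H3K9ac replicate 2 camera's direction, which follows the members' test statistics, turned (adjusted p = 0.973, range 2.22e-05 to 0.973). Protocadherins ranged from -156.2 bp to 15 bp, the latter without H3K9ac replicate 1 (adjusted p = 0.248, range 2.53e-10 to 0.248). Among named genes, none past the threshold, the difference turned at Hdac1 (-132.5 bp) and Pcdhgc5 (561.5 bp) with the window of 5 kb, and leaving out a library it ranged from -425.5 to 113.5 bp at Pcdhgc5 and Pcdhgb7 and from -168.2 to 1259.5 bp at H4c2. Apart from shorter lists and looser rules, the cause was not tested. With the replicate block 0 genes passed, 809 had an unadjusted p under 0.05 and 4 lists passed, as developmental regulators did not (adjusted p = 0.0563); deviations of libraries with the same number correlated at 0.139 over genes, which with 2 pairs shows only a shared number. Transcript starts and CpG content were not run, and unknown read depth limits every comparison of list length.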

Other observations

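The tests of longer lists, of shared background and chromatin and of regrouped libraries for the summit pileup, and the choice of the widest regions, were made only after the result was seen. Ranked by the mean length of the longest peak per library, the region of Kdm6b was followed by Tnrc18 (11671 to 11939 bp over the 4 libraries) and Setd1b, a histone methyltransferase gene that shares its region with Rhof (9537 to 13670 bp). Sall1 (8505 to 11515 bp), Trim71, a regulator of undifferentiated cells (9939 to 10376 bp), Otx2 (9227 to 9744 bp), Sox2 (7738 to 10278 bp), Hes1 (8947 to 9157 bp) and Arid1a (7889 to 8037 bp) were also among the 25 widest.

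Transfer RNA genes were the most occupied of the other gene classes, with both marks at an end of 256 of 408 (62.7%), or 167 of 300 (55.7%) of those more than 5 kb from protein-coding gene ends. Small nucleolar RNA genes had both marks at 143 of 1340 (10.7%) and pseudogenes at 190 of 9944 (1.91%). Of those more than 5 kb from protein-coding gene ends, 14 of 1064 small nucleolar RNA genes (1.32%) and 82 of 8526 pseudogenes (0.962%) had both marks.

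Regions with H3K9cr alone outnumbered those with H3K9ac alone by a ratio of 9.21. With equal numbers of peaks the ratio was 2.32 (95% interval 1.95 to 2.77, for counting error over regions only), so list length may account for part of the excess, while regrouped libraries reached 1.59. Because the remainder is neither gone nor kept in size, longer lists and a true excess of H3K9cr sites cannot be told apart. With all peaks the ratio was 4.53 within replicate 1 and 1.83 within replicate 2, a wider spread than that interval. Without H3K9ac replicate 1, which loosens the rule, 1162 H3K9cr-only and 857 H3K9ac-only regions were found. Without any other library, at least 2088 H3K9cr-only and at most 456 H3K9ac-only regions were found. H3K9ac replicate 1 had the lowest median summit pileup, 56 against 66.7 and 66.3 (H3K9cr) and 77.1 (H3K9ac replicate 2). Its smallest implied background was also the lowest, 1.58 against 1.91, 2.03 and 1.98. A lower depth of that library could give such values, but read depth was not given and this was not tested.

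Fold enrichment ranked regions more alike in libraries of one replicate number than of one mark, by 0.0376 in mean rho. For the summit pileup the difference was -0.00241, with a gap of 0.00298 between the same-mark pairs. A chromatin or library preparation shared by a number was taken to need a difference above 0.01, which was not reached. That limit was set after the result was seen. With a mean rho of 0.988 for the same mark, such a difference could hardly arise. A chromatin or library preparation shared by a number therefore stays open. The implied local background was more alike within a number by 0.619 in rho, as a background shared by libraries of one number would give. A candidate explanation is that libraries of one number were called against one input, which the sources used here do not state. No biological explanation was tested.

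Ranks of the summit pileup differed between marks in the same direction in both replicates, with a correlation of 0.142 across 22972 regions, and 0.127 when the replicates were crossed. The difference between replicate numbers correlated at 0.0149 across marks. Among the stronger regions the correlation was 0.251, which argues against weak sites near the threshold, and after trends with peak strength and length were removed it was 0.141, which argues against these trends. In limma 0 regions passed, and 1738 had an unadjusted p under 0.05 against at most 890 in the regrouped splits, of which 1 of 3 splits, the real one, gave as many, too few splits for a share under 0.05. A difference between the marks may underlie this as a hypothesis, but a difference between the antibodies and GC content were not tested and stay open.

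For the covered length of gene lists, 1 of 3 splits, the real one, gave 5 lists past 0.05, and the highest other gave 2; 3 splits are too few for a share under 0.05. The lists past 0.05 in the regrouped splits, protocadherins (adjusted p = 1.83e-04 and 1.15e-05) and developmental regulators (0.00434), are among these 5, with smaller p than by mark.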
